A study of Nostoc sp. PCC 7120 = FACHB-418 with 4 samples.

How the data were processed

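Total RNA of the nsiR3 deletion mutant of Nostoc sp. PCC 7120 was hybridised to 4 one-colour arrays, 2 at 0 h and 2 at 8 h after removal of combined nitrogen. Per the labels' protocols the cells grew at 30 °C in medium with 6 mM ammonium chloride, nitrogen was removed by filtration, RNA was isolated by hot phenol extraction, and 2 µg of DNase-treated RNA was labelled directly with Cy3 without cDNA synthesis. Groups and replicate numbers were taken from the sample titles and the treatment labels. The series' design text states that each time point had different experiments as replicates. It does not say whether a replicate number joins a 0 h and an 8 h sample, so p-values measure the spread between these samples.

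The scanner output of each array is in Cy3 intensity units, and the authors deposited it as written by Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09, per the file headers. Per the file headers the processed intensity is background-subtracted and spatially detrended, with a surrogate value where a spot was not above background. The authors also deposited a value table on the log2 scale. The submitters' processing notes name limma without a version, and the steps are not given in the sources used here. Set against the scanner intensities, each column of that table had the rank order of mean signal minus background median of the same array, and the medians of its columns were 9.34, 9.34, 9.34 and 9.34. The sorted values of the columns differed from their mean at the same rank by at most 0.00243 over all spots, with 5th, 25th, 75th and 95th percentiles of 7.14, 8.53, 10.5 and 13.0. It is therefore a background-corrected log2 intensity, quantile normalized over all 62976 spots, control spots included, and not centred per gene. These properties were read from the values.

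Of 62976 spots, 1439 control spots were left out, as were the 141 to 274 spots per array that the scanner software marked as outliers. Log2 processed intensities of repeated spots of a probe were averaged, the array's 75th percentile over the 55201 distinct probes was subtracted, and the probes of a transcript were averaged. The percentile was taken over probes and not over spots because the 10 probes of the 6 named small RNAs were printed on about 618 spots each and filled 10.1% of the non-control spots. Fewer than 50% of probes were well above background on 3 of the 4 arrays, so scaling to the probes well above background on all arrays was tried as an alternative. A probe counted as well above background where more than 50% of its spots carried the scanner's mark. Transcripts with at least 1 such probe on 2 or more arrays were kept. At most 5 probes per array were saturated and no changed transcript had a saturated probe. Among 1003 changed protein-coding genes with 2 or more probes, the probes did not all change in the same direction in 16. Of the tested protein-coding genes, 95 shared a probe sequence with another transcript, and their signals cannot be assigned to a single copy. Of the changed transcripts, 246 were not well above background on any array of 1 time point, and for these a lower bound is given beside the fitted change, which rests on dim values and can exceed the true fold.

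The array identifies transcripts by genome coordinates on the sequence version of assembly ASM970v1. Of 6079 gene features, 5833 matched 1 reference gene by position, 4799 exactly and 1034 on the stop codon side only, and 940 had a symbol. The 246 without a match kept the array's name. Of the gene features, 57 are annotated as pseudogenes and were counted with the other transcripts. The remaining 6022, the 246 without a match included, were counted as protein-coding genes, so this class may hold genes of other types. The array also covers 9372 intergenic regions by strand, 4379 antisense windows of 147 bases and 6 named small RNAs. The named small RNAs were placed by a shared stretch of 20 bases with the probes of an intergenic region. Antisense windows carry no replicon name, and 3499 were placed opposite 1 gene.

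Differences were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the time point as the only term, and p-values were adjusted by Benjamini-Hochberg over all 13647 tested transcripts. The fit had 2 residual degrees of freedom per transcript and 4.07 prior degrees of freedom. An exact permutation of 2 against 2 arrays cannot go below a two-sided p of 0.333, so calls rest on limma's pooled variance. The 20 gene lists were fixed before the data were examined, as were the design, the rule for named genes and most alternatives. Lists with at least 3 tested members were tested with camera over the protein-coding genes with a preset correlation of 0.01, adjusted over the 19 lists tested. camera with an estimated correlation and fry were alternatives. The estimated correlation leaves the test the 2 residual degrees of freedom of the fit.

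The file headers put the arrays on 2 slides, scanned on different days. Slide 1 held both arrays numbered replicate 1 and slide 2 both numbered replicate 2, so slide, scan and replicate number are the same split. The deviations of same-numbered arrays from their group means correlated with r = 0.565 across transcripts, which are not independent. The slide is a technical batch that holds both time points, so values with the slide as a block and within each slide are given.

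The named genes were alr0540, ntcA, hetR, nrrA, hetC, hetP, nirA, glnA, nblA, nifH and hepA whatever their result. To these were added the 12 protein-coding genes with the largest rise and the 12 with the largest fall among those that passed and changed alike on both slides, and by the same rule 5 and 5 other transcripts. Up to 4 members of each list with the smallest adjusted p and the small RNAs named on the array completed the rule.

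Alternatives covered normexp background correction with an offset of 50, quantile and median normalization, no filter and a stricter filter, the median of probes, single probes, the slide as a block, eBayes with trend and robust options, stricter thresholds, the authors' normalized values, and leaving out each array. With 1 array left in a group, limma takes the lone array to vary like the other group. The pipeline was tested on simulated data for 13647 transcripts with 50 changed transcripts per fold size. It called 4% of changes of 2-fold, 80% of 4-fold, 98% of 16-fold and 98% of 32-fold for this comparison, with 3 calls among 13435 unchanged transcripts. A simulated 2-fold shift of a 12-gene list was called and 0 of 18 other lists were. Far fewer transcripts changed in the simulation than passed in the data, and simulated values varied independently with no slide effect. These results may therefore not hold for the arrays.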

Results

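The arrays recorded the transcriptome of a deletion mutant of Nostoc sp. PCC 7120 that lacks the small RNA gene nsiR3. Nostoc sp. PCC 7120 is a filamentous cyanobacterium in which some cells of a filament differentiate into nitrogen-fixing heterocysts when combined nitrogen runs out. Cultures were grown at 30 °C with 6 mM ammonium, and combined nitrogen was then removed by filtration. RNA was taken at 0 h and at 8 h without combined nitrogen. Each time point had 2 replicate arrays from different experiments, which gave 4 one-colour Cy3 arrays in all. Each array carried 55201 distinct probes for 19836 transcripts. RNA was labelled directly, so each strand was read separately. The share of probes well above background was 49.7% and 41.8% on the 0 h arrays and 55.3% and 44.8% on the 8 h arrays (replicates 1 and 2). A transcript was tested where at least 1 of its probes was well above background on 2 or more arrays, which left 13647 transcripts, 5011 of them protein-coding genes. The replicate arrays correlated with r = 0.966 at 0 h and r = 0.967 at 8 h across the tested transcripts. The number of arrays limits the precision of every value. All changes are log2 differences, 8 h minus 0 h, with their standard errors from limma on 2 against 2 arrays, and no wild-type array was analysed here.

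The deleted small RNA was examined first, which the design planned as a check of the strain label. Its probe was printed on 618 spots, and 0% of the spots kept were well above background on any of the 4 arrays. Its mean signal was 50.8 and 77.8 units on the 0 h arrays and 55.0 and 77.7 units on the 8 h arrays. The lowest signal of a probe well above background was 193 and 390 units at 0 h and 240.0 and 339 units at 8 h. The probe falls in the intergenic region at 5451878 to 5452195 on the plus strand of the chromosome (assembly ASM970v1), between asl4557 and all4558. The array's other probes for this strand of the region were not well above background on any array either. The labels do not give the extent of the deletion, so it was not checked that these probes lie inside it. No wild-type array shows that the probe detects the RNA. NC-7, another small RNA on the array, had near equal signals (50.9 and 77.8 units at 0 h, 54.9 and 77.6 units at 8 h). On 0 h replicate 2 the kept spots of the NsiR3 probe had a log2 SD of 0, so that signal is a floor value. The near equality with NC-7 can reflect each array's floor. The low signal therefore cannot by itself check the strain label.

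**Figure D1:**
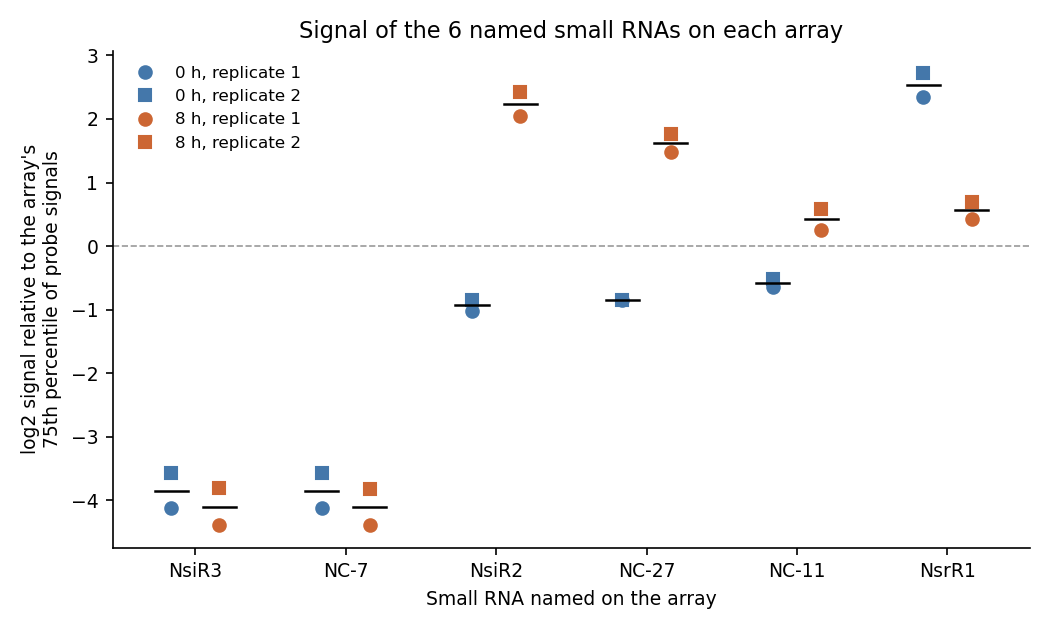
Signal of the 6 small RNAs that the array names, as log2 signal relative to the array's 75th percentile of probe signals, for each of the 4 arrays (circles, replicate 1; squares, replicate 2; bars, mean of 2). NsiR3 and NC-7 lie below -3.5 on every array and are not well above background, while the means of NsiR2 go from -0.93 at 0 h to 2.23 at 8 h.

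The comparison of 8 h with 0 h asks which transcripts of the mutant respond to the loss of combined nitrogen. All 21 genes listed for the heterocyst envelope polysaccharide and 13 of 16 for the uptake of nitrogen sources rose, while all 21 phycobilisome genes, all 9 ATP synthase genes and 20 of 29 ribosomal protein genes fell. These lists passed a test with a preset correlation and none passed with an estimated correlation (lowest adjusted p = 0.295). The estimated correlation leaves that test only the 2 residual degrees of freedom of the fit. In limma's fit 1006 of 5011 protein-coding genes passed an adjusted p of 0.05, of which 493 rose and 513 fell. The fitted change was 2-fold or more for 402 of the genes that rose and 378 of those that fell, and 8-fold or more for 71 and 53. These counts do not use the lower bounds, some of which lie under these folds. The arrays came from 2 slides, each of which held 1 array per time point. With the slide as a block, 1373 genes passed, 636 up and 737 down. The count fell to 435 without 0 h replicate 2 and to 641 without 8 h replicate 1. The median change of all tested transcripts was -0.15, and scaling to probes well above background on all arrays moved it to -0.02. That scaling was chosen after the data were seen and gave 569 genes up and 377 down, so the share of falls among the calls was 39.9% in place of 51.0%. The share went the other way with the authors' normalized values (477 up and 1129 down, 70.3%) and with the percentile over spots (337 up and 2228 down, 86.9%).

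**Figure D2:**
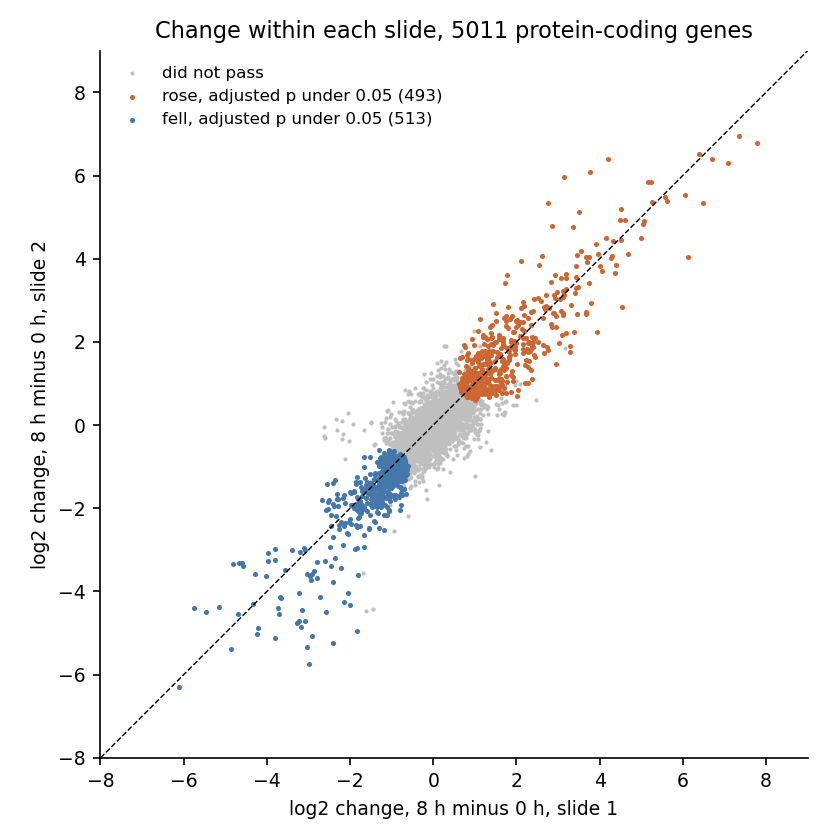
Change of each of the 5011 tested protein-coding genes within slide 1 (x axis) and within slide 2 (y axis), as log2 signal at 8 h minus 0 h. Each point is a gene, the dashed line marks equal change, and the 493 genes that rose and the 513 that fell at an adjusted p under 0.05 are coloured.

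The largest fitted rises came from the gene cluster alr2822 to alr2841, at 3436657 to 3462973 on the chromosome, which encodes synthesis and export of the envelope polysaccharide that surrounds heterocysts. All 21 genes of the fixed list for this layer rose, with a median change of 5.31, or 4.23 when genes below background at 0 h were set at their lower bound. Among the 12 protein-coding genes with the largest fitted rise, 11 lay in this cluster, but the order of genes with a bound is not established. The bounds of hepA and alr2836 lie below the folds of alr2515 (26.0-fold), alr2516 (27.3-fold) and nrrA (18.2-fold) outside it. Those of alr2822, alr2833, hepC and alr2828 lie below the folds of alr2515 and alr2516. alr2516 was itself well above background on 1 array at 0 h. alr2825 changed by 7.28 ± 0.40 (at least 49.7-fold, adjusted p = 0.000725), alr2826 by 7.15 ± 0.24 (at least 40.4-fold) and alr2827 by 6.69 ± 0.47 (at least 53.6-fold). For alr2831 the change was 6.55 ± 0.32 and all arrays were above background. The polysaccharide exporter gene hepA (alr2835) rose at least 10.73-fold (5.50 ± 0.23, adjusted p = 0.000428) and its neighbour hepC (alr2834) at least 19.7-fold. The rest of the 12, with alr2514 described below, were alr2828 (at least 23.5-fold), alr2833 (at least 19.0-fold), alr2822 (at least 18.8-fold), alr2836 (at least 11.1-fold) and alr2830 (5.78, above background on 1 array at 0 h). The list's shift had an adjusted p of 2.06e-23 in limma's camera test with a preset correlation (median 5.24 on slide 1 and 5.34 on slide 2, adjusted p = 3.51e-22 with the slide as a block). It had an adjusted p = 0.295 with an estimated correlation. A bound is given where a transcript was not well above background on any array of 1 time point. It sets the mean of the brighter time point against the mean, over the dimmer arrays, of the transcript's own signal or the lowest signal well above background, whichever is higher. No bound is given where 1 array of the dimmer time point was well above background. The fold of such a transcript rests in part on a dim value and can also exceed the true fold.

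Of 17 tested regulators of nitrogen control and heterocyst differentiation, 7 rose, none fell and 10 did not pass. Adjusted over the list alone, 10 rose. The response regulator gene nrrA (all4312) changed by 4.18 ± 0.29 (18.2-fold, adjusted p = 0.000926), asr1734 by 3.82 ± 0.25 and hetP (alr2818) by 3.09 ± 0.23. At 0 h hetP was well above background on 1 array. ntcA (alr4392), which encodes the global nitrogen regulator, changed by 1.93 ± 0.22 (3.82-fold, adjusted p = 0.00463). hetR (alr2339), the master regulator gene of heterocyst differentiation, changed by 1.44 ± 0.26 (adjusted p = 0.0181). hetC (alr2817) had a change of 0.86 ± 0.22 with an adjusted p of 0.0506, which did not pass, and passed with the slide as a block (adjusted p = 0.0461). The list was shifted upward in camera (adjusted p = 0.000186, medians 0.74 and 0.65 on slides 1 and 2, adjusted p = 0.000217 with the block). With an estimated correlation it had an adjusted p = 0.295.

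Of the 11 tested genes for heterocyst glycolipids, 4 rose and 7 did not pass, also when adjusted over the list alone. The 3 genes of the devBCA exporter were not well above background at 0 h. devB (alr3710) changed by 4.04 ± 0.26 (at least 5.45-fold), devA (alr3712) by 3.41 ± 0.24 (at least 3.78-fold) and devC (alr3711) by 2.50 ± 0.29 (at least 1.84-fold). hglK (all0813) changed by 1.24 ± 0.22. The list's shift had an adjusted p of 0.0107 in camera (0.0129 with the slide as a block, medians 0.50 and 0.51) and an adjusted p = 0.295 with an estimated correlation. Among transcripts above background on all 4 arrays the call was lost (6 genes, 1 up, median -0.08, adjusted p = 0.492), where the filter itself left out devA, devB and devC for their dim signal at 0 h. Of the 7 tested genes of the heterocyst respiration and oxygen protection list, 6 rose, and 7 did when adjusted over the list alone. alr2514, alr2515 and alr2516, the cytochrome c oxidase cluster at 3021198 to 3024630, changed by 5.51 ± 0.27 (at least 19.9-fold), 4.70 ± 0.28 and 4.77 ± 0.32. At 0 h alr2516 was well above background on 1 array. The flavodiiron protein gene flv1B (all0177) changed by 1.84 ± 0.22, at least 1.42-fold. This list was shifted upward in camera (adjusted p = 1.72e-06, medians 1.97 and 2.11 on the slides, adjusted p = 1.61e-06 with the block), with an adjusted p = 0.295 with an estimated correlation.

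Most genes of nitrogen fixation proper were too dim to test or did not pass at 8 h. Of 14 nitrogenase region genes on the array only 7 were bright enough to be tested, 1 of these rose and 6 did not pass, also when adjusted over the list alone. The gene that rose was all1432 (2.08 ± 0.37, at least 1.81-fold). nifH (all1455), which encodes the dinitrogenase reductase, had a change of 0.50 ± 0.65 (adjusted p = 0.635), with -0.23 on slide 1 and 1.24 on slide 2. Without 8 h replicate 1 its change was 1.54 and passed (adjusted p = 0.0222). The changes of all1437, all1435 and all1457 were 0.48, -0.25 and -0.21. The list did not pass in camera (adjusted p = 0.583, and 0.499 with the slide as a block), its median of -0.09 lay below 0 while its mean of 0.33 lay above it, and the medians were -0.23 and 0.11 on the slides. It passed only without 8 h replicate 1 (adjusted p = 0.0428).

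Of the 16 genes for uptake and reduction of nitrogen sources, 13 rose and 3 did not pass, and 15 rose when adjusted over the list alone. The nitrite reductase gene nirA (alr0607) changed by 3.68 ± 0.44 (12.9-fold, adjusted p = 0.00573). nrtA (alr0608), of the nitrate transporter, changed by 3.20 ± 0.36 (9.20-fold) and was well above background on 1 array at 0 h. Of the ammonium transporter genes, alr0990 changed by 3.17 ± 0.20 and alr0991 by 1.81 ± 0.22, while their neighbour alr0992 had a change of 0.60 that did not pass (adjusted p = 0.164). The list was shifted upward (camera adjusted p = 1.27e-09, medians 1.43 and 1.83 on the slides, adjusted p = 9.76e-10 with the block). It had an adjusted p = 0.295 with an estimated correlation. The 10 genes of nitrogen assimilation went both ways, with 2 up, 2 down and 6 not passing over all transcripts and over the list alone. The regulator genes ntcB (all0602) and asr0485, which encodes PipX, changed by 2.91 ± 0.24 and 2.22 ± 0.19. asl2329, which encodes an inactivating factor of glutamine synthetase, fell by 3.82 ± 0.22 (14.1-fold, adjusted p = 0.00074), and alr0573 fell by 1.13 ± 0.20. The glutamine synthetase gene glnA (alr2328) had a change of 0.58 ± 0.23 that did not pass (adjusted p = 0.144). The list as a whole did not pass in camera (adjusted p = 0.585, and 0.539 with the block). alr0540 (pruA) had a change of -0.23 ± 0.19 that did not pass either (adjusted p = 0.439), with -0.33 on slide 1 and -0.14 on slide 2.

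All 21 genes for phycobilisomes, the light-harvesting antennae of cyanobacteria, fell, with a median of -2.16 (-2.35 on slide 1 and -1.88 on slide 2). The phycoerythrocyanin cluster fell most. alr0524 fell by 4.07 ± 0.40 (16.8-fold, adjusted p = 0.00273), alr0525 by 3.98 ± 0.38, alr0526 by 3.93 ± 0.24 and alr0527 by 3.62 ± 0.30. At 8 h alr0527 was well above background on 1 array. The shift had a camera adjusted p of 4.46e-12 (1.6e-11 with the block) and an adjusted p = 0.435 with an estimated correlation. nblA (asr4517), whose product directs phycobilisome breakdown, was the tested gene of its list and rose by 3.89 ± 0.35 (14.8-fold, adjusted p = 0.00211). Of 13 photosystem II genes 9 fell and 4 did not pass, also over the list alone. psbD (alr4290) fell by 1.42 ± 0.19, alr4548 by 1.28 ± 0.19, psbB (all0138) by 1.37 ± 0.21 and psbE (asr3845) by 1.14 ± 0.18. alr4548 is also annotated as psbD, and both alr4290 and alr4548 had 2 of 3 probes with a sequence shared with another transcript. Their falls may therefore not be separate measurements. The list's camera adjusted p was 8.03e-05 (2.73e-05 with the block, medians -1.21 and -1.26), and it had an adjusted p = 0.295 with an estimated correlation and 0.114 with the authors' normalized values. With quantile normalization 2 of the 13 photosystem II genes passed (median -0.57 in place of -1.14), with normexp and quantile normalization 6 (median -0.49) and with the authors' values 5 (median -0.42). Of 10 photosystem I genes 5 fell and 5 did not pass, and 9 fell when adjusted over the list alone. alr5314 fell by 1.19 ± 0.19, psaE (asr4319) by 0.99 ± 0.23, psaL (all0107) by 0.98 ± 0.22 and psaB (alr5155) by 0.97 ± 0.24. The list's camera adjusted p was 0.000612 (0.000931 with the block, medians -0.97 and -0.71), and it had an adjusted p = 0.491 with an estimated correlation. This call was lost with quantile normalization (adjusted p = 0.258), with normexp and quantile normalization (0.228) and with the authors' normalized values (0.808), where 1 of the 10 genes passed in each case and the median, -0.83 in the main scaling, was -0.20, -0.19 and -0.17.

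The 9 ATP synthase genes fell, with a median of -1.86, and all 9 also did over the list alone. all0006 fell by 2.02 ± 0.38, all0008 by 1.86 ± 0.34, all0010 by 1.57 ± 0.28 and all5039 by 1.29 ± 0.24. With quantile normalization 5 of the 9 ATP synthase genes passed (median -1.42), with normexp and quantile normalization 8 (median -1.34) and with the authors' values 8 (median -1.30). The camera adjusted p was 0.00014 (1.38e-05 with the block, medians -1.70 and -2.02) and the adjusted p = 0.463 with an estimated correlation. Of 29 ribosomal protein genes 20 fell and 9 did not pass, and 24 fell when adjusted over the list alone. all4200 fell by 1.96 ± 0.23, asl4206 fell by 1.94 ± 0.25, all4201 by 1.93 ± 0.23 and all4215 by 1.73 ± 0.21 (adjusted p from 0.00514 to 0.00715). The list's camera adjusted p was 5.17e-10 (7.79e-11 with the block, medians -1.62 and -1.87), and it had an adjusted p = 0.441 with an estimated correlation. Of 12 tested carbon fixation genes 7 fell and 5 did not pass, and 11 fell over the list alone. alr1041 fell by 1.51 ± 0.23, all0864 by 1.41 ± 0.33, all0865 by 1.33 ± 0.23 and rbcX (alr1525), of the RuBisCO operon, by 1.24 ± 0.29. The camera adjusted p was 0.000263 (2.78e-05 with the block, medians -1.05 and -1.28), with an adjusted p = 0.435 with an estimated correlation and 0.0527 with the authors' normalized values. With quantile normalization 3 of the 12 carbon fixation genes passed (median -0.65 in place of -1.16), with normexp and quantile normalization 3 (median -0.62) and with the authors' values 4 (median -0.64). Of the 7 NDH-1 genes, 1 fell and 6 did not pass, while 7 fell when adjusted over the list alone. alr0223 fell by 0.83 ± 0.19 (adjusted p = 0.0398), and the changes of alr0226, alr0224 and all3840 were -0.72, -0.69 and -0.64. With the slide as a block 6 of the 7 genes passed, among them alr0226, alr0224 and all3840 (adjusted p = 0.0368, 0.0422 and 0.0454), and with quantile normalization 0 did. The list's camera adjusted p was 0.00599 (0.00688 with the block, medians -0.65 and -0.67), with an adjusted p = 0.435 with an estimated correlation and 0.158 with the authors' normalized values.

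Of 11 genes of the iron and oxidative stress list 7 fell, 2 rose and 2 did not pass, also over the list alone. The genes that fell included those that cyanobacteria induce under iron limitation. isiA (all4001), which encodes a chlorophyll-binding antenna protein, fell by 4.76 ± 0.25 (27.1-fold, adjusted p = 0.000646), isiB (alr2405), which encodes flavodoxin, by 3.39 ± 0.25, and all4002 by 3.52 ± 0.22. The manganese catalase gene katB (alr3090) fell by 4.37 ± 0.59 (20.7-fold), with -2.995 on slide 1 and -5.75 on slide 2. At 8 h katB was well above background on 1 array. alr3808 rose by 3.49 ± 0.20. The list's camera adjusted p was 0.0039 (0.0107 with the block, medians -1.49 and -1.38), with an adjusted p = 0.295 with an estimated correlation, 0.173 with the authors' normalized values and 0.140 with the percentile over spots. Other genes next to isiA were among the 12 largest fitted falls, with all3999 at -5.07 (at least 8.04-fold lower) and all4000 at -4.97. The largest fitted fall of any protein-coding gene was that of PCC7120DELTA_RS32395, a gene without a symbol at 1577189 to 1577344, which fell by 6.21 ± 0.19 (73.8-fold, adjusted p = 0.000362). all0458 (-5.12, at least 8.17-fold lower), all0459 (-4.64), asr4653 (-4.62), all0393 (-4.54), asr1134 (-4.46), all0390 (-4.32) and alr0198 (-4.19) completed the 12. At 8 h all0393 was well above background on 1 array.

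The remaining fixed lists did not pass in camera, with or without the slide as a block. Of 9 sigma factor genes 3 rose, 2 fell and 4 did not pass, and 3 rose and 4 fell over the list alone (camera adjusted p = 0.583, and 0.539 with the block). sigC (all1692) changed by 2.42 ± 0.22, sigB (all7615) by 2.20 ± 0.24 and sigG (alr3280) by 1.19 ± 0.21, while sigD (alr3810) fell by 0.95 ± 0.18. Of 11 septum and cell wall genes 1 rose, the amidase gene amiC1 (alr0092, 1.06 ± 0.24), and 10 did not pass, with 0.52 for ftsQ (alr3857), 0.48 for sepJ (alr2338) and -0.41 for fraE (alr2394) (camera adjusted p = 0.4997, and 0.499 with the block). None of the 5 oxidative pentose phosphate genes passed, over all transcripts or over the list alone, and gnd (alr5275), tal (all4020), opcA (all4018) and zwf (all4019) had changes of 0.65, -0.50, -0.30 and -0.20 (camera adjusted p = 0.850, and 0.828 with the block). Of 6 chaperone genes 1 fell, alr1896 (-1.27 ± 0.20), and 5 did not pass, with -0.49 for htpG (alr2323), 0.49 for alr1742 and -0.36 for groES (alr3661) (camera adjusted p = 0.4997, and 0.499 with the block). In all, 13 of the 19 lists that could be tested passed with the preset correlation of 0.01. With an estimated correlation 0 passed (lowest adjusted p = 0.295), where the test keeps only 2 residual degrees of freedom. For photosystem II the estimated correlation was 0.012, near the preset. Its unadjusted camera p still went from 2.54e-05 to 0.0531. A list's failure there does not by itself show that correlation between genes accounts for its shift. limma's fry test, which asks whether a list's genes move one way on balance, called 11 lists. It did not call photosystem I (adjusted p = 0.064), ATP synthase (0.0848) or the ribosomal proteins (0.0531), and it called the chaperones (0.045).

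**Figure D3:**
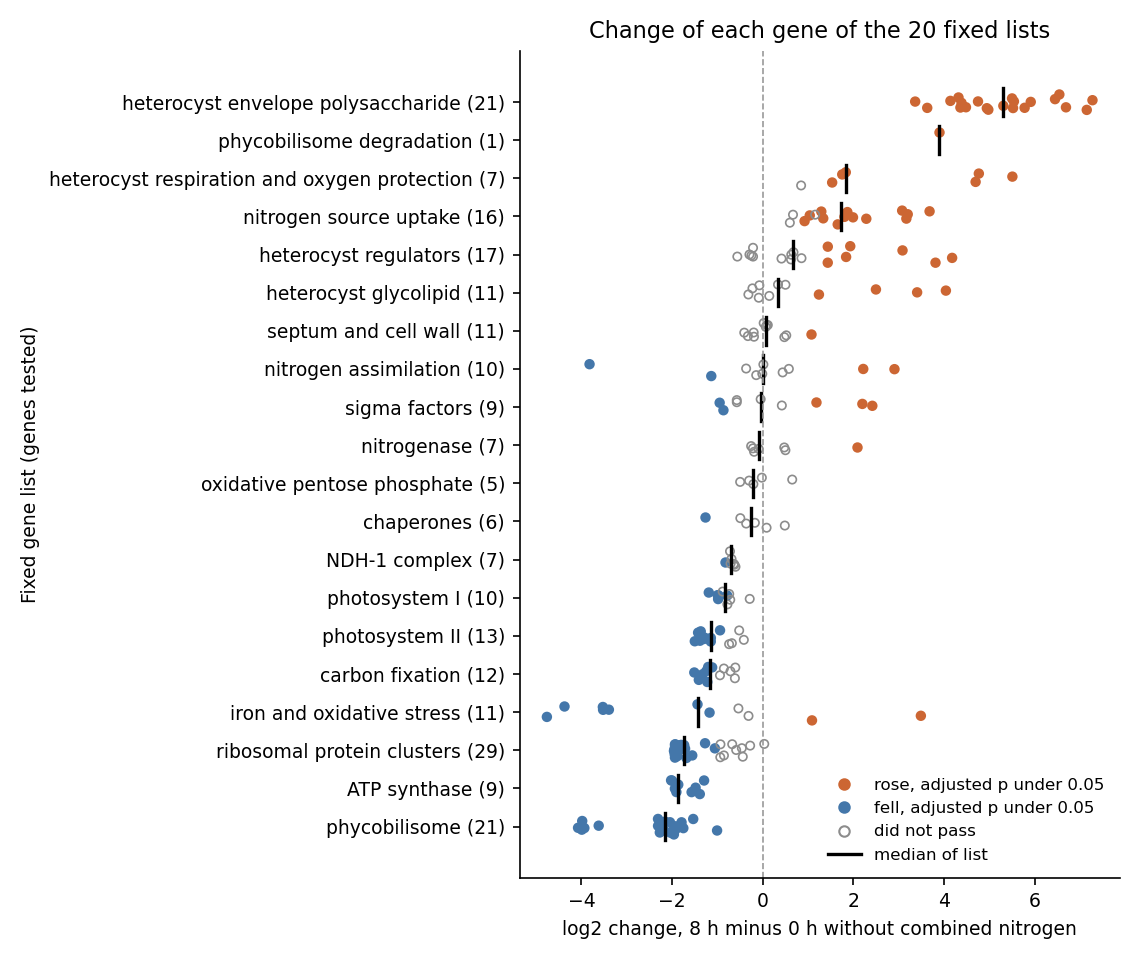
Change of each tested gene of the 20 fixed lists, as log2 signal at 8 h minus 0 h (points, genes; filled, adjusted p under 0.05; black bars, median of the list; number of tested genes in brackets). The 21 envelope polysaccharide genes lie between 3.37 and 7.28, and the 21 phycobilisome genes between -4.07 and -1.01.

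Transcripts other than protein-coding genes were counted apart. Of 8636 tested, 1016 passed, with 461 up and 555 down. They comprised 702 of 5605 intergenic regions (282 up, 420 down), 308 of 2992 antisense windows (174 up, 134 down), 4 named small RNAs and 2 pseudogenes. With the slide as a block 1577 passed, 636 up and 941 down. The count fell to 588 without 0 h replicate 1, to 382 without 0 h replicate 2 and without 8 h replicate 1 to 306 up and 303 down. The share of falls was 54.6%, and depended on the scaling. It was 41.7% of 920 calls scaled to probes above background on all arrays, 65.3% with normexp, 75.1% with the authors' normalized values and 93.7% with the percentile over spots.

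The 5 intergenic regions with the largest fitted rise were on the strand of a neighbouring gene. 4 lay in the envelope polysaccharide cluster, at 3446916 to 3446984 between alr2830 and alr2831 (6.58 ± 0.25, at least 21.9-fold), at 3443246 to 3443321 (5.83 ± 0.44, at least 30.0-fold), at 3444351 to 3444427 (5.54 ± 0.22, at least 11.7-fold) and at 3441921 to 3442030 (5.43 ± 0.25, at least 9.74-fold). The other lay at 1693375 to 1693429 on the minus strand, between all1432 and all1433 (5.20 ± 0.30, at least 14.3-fold). The regions with the largest fitted fall flanked genes named above. The region at 1577078 to 1577188, directly before PCC7120DELTA_RS32395, fell by 6.67 ± 0.26 (at least 22.2-fold) and the region at 1577345 to 1577558, directly after it, by 4.94 ± 0.19. Those between all3999 and all4000, between alr0198 and alr0199 and between all0393 and all0394 fell by 4.89 ± 0.36, 4.82 ± 0.49 (at least 10.2-fold) and 4.82 ± 0.54. At 8 h the region between all0393 and all0394 was well above background on 1 array, as was the region directly after PCC7120DELTA_RS32395. Among the small RNAs that the array names, NsiR2 rose by 3.16 ± 0.22 (8.95-fold, adjusted p = 0.000912), NC-27 by 2.47 ± 0.20 (5.54-fold) and NC-11 by 1.002 ± 0.21 (adjusted p = 0.028). NsrR1, a nitrogen stress-repressed small RNA, fell by 1.96 ± 0.23 (3.90-fold, adjusted p = 0.00479). NC-7 was, like NsiR3, not well above background on any array.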

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

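The alternatives that scale to probes above background or over spots, and the joint normexp, quantile and block setting, were chosen after seeing the data. The mixed model with slide as a random block could not be fitted with 4 arrays and was not run. All 1006 and 1016 main calls rest on 2 arrays per group. With 1 array left out, 435 to 763 protein-coding genes, 382 to 753 other transcripts and 13 to 14 lists passed, where fewer arrays also lower the power. No filter gave 647 protein-coding and 589 other transcripts, with more dim transcripts in the adjustment. An adjusted p of 0.01 left 331 and 281. The authors' normalized values gave 1606 (70.3% falls) and 1828, and 8 lists. The 75th percentile over spots gave 2565 (86.9% falls) and 4418. The replicate block (slide) gave 1577 other transcripts and 1373 protein-coding genes, of which 999 were among the main calls, and changed no list's call. Together with normexp and quantile normalization the block gave 1760 and 2056. The other settings stayed within 1.5 times of the main counts, and single probes gave 1047 genes. Camera with an estimated correlation called 0 lists. The nsiR3 probe was brighter than 9.59% of probes on average over the 4 arrays, 1.96% with normexp and quantile and 1.92% with the authors' values. In the main setting the share was 12.5% and 0% on the 0 h arrays and 11.6% and 14.2% on the 8 h arrays. The 0% comes from 0 h replicate 2, where the probe's spots had an SD of 0, so ties at the floor affect this mean. Among the named genes, those whose direction turned had not passed. The glycolipid list lost its call with the strict filter (adjusted p = 0.492, median -0.08), which leaves out genes dim at 0 h, and at a threshold of 0.01 (adjusted p = 0.0107). Its median, 0.34, was -0.15 with the percentile over spots, where the call stayed. With normexp and quantile the medians of the envelope, nitrogen uptake and respiration lists were 3.35, 1.02 and 0.88 in place of 5.31, 1.73 and 1.84, and their calls stayed. With 1 array left out, all1455 changed by -0.537 to 1.54, all1437 by -0.054 to 1.01, all1457 by -0.498 to 0.072 and all4019 by -0.430 to 0.022. alr3857 changed by -0.0018 and alr2338 by -0.041 with the authors' values, and all1437 and alr2338 by -0.0094 and -0.0074 with the percentile over spots. alr3661 changed by 0.033 with normexp and quantile (with or without the block), 0.15 with quantile and 0.085 with the authors' values. Except where stated, the cause was not tested. Signal over background limits the comparison, since 8 of 19 glycolipid genes and 7 of 14 nitrogenase genes on the array were too dim to test.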

Other observations

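The tests on phosphate genes were chosen after the values were seen, as were the gene groups formed here from reference symbols and the antisense windows named. Of 7 tested pst genes, which encode the high-affinity phosphate transporter, 5 fell and 2 did not pass (median -2.71, camera adjusted p = 0.000529 over 7 such groups, adjusted p = 0.489 with an estimated correlation). pstS (all4575), the phosphate-binding protein gene, fell by 4.07 ± 0.29 and the second copy all0911 by 3.90 ± 0.50 (at least 5.32-fold lower). Of 17 genes of heme and chlorophyll synthesis 8 fell and 9 did not pass (median -0.89, camera adjusted p = 0.000119), and of 7 cys genes 5 fell and 2 did not pass (median -1.23, camera adjusted p = 0.017). With an estimated correlation the adjusted p was 0.489 for each of the 7 groups. The trp genes (adjusted p = 0.0174) and the ilv and leu genes (0.0349) passed in camera, and the pur genes (0.0538) and the fab and acc genes (0.0574) did not, and none of these passed with an estimated correlation (adjusted p = 0.489).

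Antisense windows held several of the larger rises outside coding genes. The window at 5469489 to 5469635 on the plus strand, which reaches into the end of all4575 from the gap between pstC and pstS, rose at least 9.25-fold (adjusted p = 0.000725). The window opposite alr0530, a gene of the phycocyanin cluster, rose by 3.66 ± 0.42 while alr0530 fell by 2.31 ± 0.26. The window opposite all1549 rose by 4.46 ± 0.22, with a change of -0.09 in the gene that did not pass. Windows opposite the cytochrome oxidase gene alr2514 rose with it (3.02 ± 0.24). The hypothesis that antisense RNA changes against the gene it covers was tested across 2059 pairs, which are not independent. The correlation of changes was r = -0.04 (-0.0372), which does not decide. Of 36 windows that passed opposite a gene that passed, 26 changed against the gene and 10 with it, over 29 genes (Fisher's exact test, two-sided p = 0.014). The test takes windows as independent, but some overlap or lie opposite the same gene, so its p-value can overstate the evidence.

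Changes in intergenic regions followed the neighbouring gene of the same strand. Across 4099 regions with a flanking gene on their strand, changes of region and gene correlated with r = 0.761, and of 610 such regions that passed, 429 had such a gene that changed in the same direction (70.3%). Of 3763 regions with a flanking gene on their strand that did not pass, 17.7% had such a gene that passed in either direction. A signal from the other strand is argued against, since regions with both genes on the other strand gave r = -0.0065 over 1090 regions. Many intergenic calls may therefore be leaders, trailers or read-through of genes rather than separate RNAs. In 176 of the 610 no flanking gene on the strand had passed, and another 88 regions passed between genes of the other strand.

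Falls made up a larger share of the calls with the authors' normalized values (1129 against 477, 70.3%) than in the scaling over distinct probes (513 against 493, 51.0%). Whether the authors' background handling is the cause was not decided. Normexp values quantile normalized over the non-control spots gave 70.5%. They keep each array's rank order of signal minus background, as the authors' values do, so a near equal share was largely fixed in advance. When the authors' values were quantile normalized again over distinct probes the share was 46.8%. This is consistent with an effect on the split of the probes repeated over many spots, such as the 10 small RNA probes on 10.1% of the non-control spots. The median change of all transcripts was -0.153 with the authors' values and -0.042 after normalizing them again over distinct probes. It was -0.148 in the main scaling over distinct probes. For protein-coding genes the median was -0.176 with the authors' values and -0.097 in the main scaling. The share did move with the choice of spots or distinct probes. Normexp values gave 70.5% falls when quantile normalized over spots and 46.7% over distinct probes. The 75th percentile gave 86.9% over spots and 51.0% over distinct probes. By what route the repeated probes act on the split was not tested.

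The fall of 5 pst genes is hard to place, since 7 of 11 genes of the iron and oxidative stress list fell as well, while 2 rose. That list did not pass with an estimated correlation (adjusted p = 0.295). A scaling effect is argued against, since the median of the pst genes was -1.93 or lower in every setting, while the median of all transcripts moved between -0.63 and -0.02. The medium exchange that may go with filtration is a candidate explanation. It cannot be told apart from nitrogen loss, because no array had filtered cells with ammonium. The median of -1.44 in the iron and oxidative stress list does not decide. That list is not made of iron genes alone, and its falls include prxA (-1.44) and sodA (-1.17). A response to nitrogen loss itself stays open and was not tested.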
